A study of Saccharomyces cerevisiae with 57 samples.

How the data were processed

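The series measured mRNA in budding yeast on spotted oligonucleotide arrays with 2 colours, 57 arrays in all. Each array held total RNA of 1 strain in one dye and a common reference RNA in the other, per the labels. The scanner values deposited for each array are intensities per spot, with a mean signal and a median local background in Cy5 and in Cy3, per the file headers. The scanner and the image software are not given in the sources used here. A second file per array holds intensities that the authors normalized within the array, per the file headers, by a method that the headers do not state. The authors' table of the whole series holds log2 ratios per spot, which equal the log2 of the normalized intensities turned to strain over reference on every array, as found by setting each column against its own array. Column medians of that table lay between -0.000698 and 0.0337 (median 0.0137), so its scale, direction and centring are known from the values, and its normalization method stays unknown. The protocol texts hold no measurement and were not used. The table has 0 columns of samples outside the 57.

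Groups were taken from the strain, plasmid marker and SUB1 deletion in the labels, which gave 35 groups, 17 with 2 or more arrays and 18 with 1. In the LEU2 wild type the titles of arrays 2 and 3 add +SUB1 and that of array 1 does not, and all were taken as 1 group. Arrays 2 and 3 had the lowest mean correlations with group mates in the series, 0.767 and 0.751. The strain was in Cy5 on 25 arrays and in Cy3 on 32, and the reference was pool 1 on 29 arrays and pool 3 on 28, per the labels. Each ratio was turned to strain over reference by the dyes in the labels, and the deposited dye-named columns gave the same orientation. The groups, the comparisons, the gene lists and most alternatives were chosen before the data were examined, and those chosen later are named as such.

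Of 15552 spots on an array, 12776 held yeast probes and 2776 were controls. The yeast spots form 6388 probes with 2 spots each. Names came from the platform annotation, updated through a table of yeast genes: 5326 probes had 1 gene name, 0 had several and 1062 had none. Of the named, 5266 matched a current symbol and 58 an older one, and the rest kept the annotation's name. This gave 5311 genes, of which 15 had 2 probes that were averaged.

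Background was corrected with the normexp method (offset 50) on all spots, and each array was normalized by global loess (span 0.3) with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Duplicate spots were averaged. The SD between duplicate spots was 0.0257 to 0.0960 on the log2 scale, and 0 to 29 gene spots per array were saturated and kept. Correlation with the authors' log2 ratios was 0.873 to 0.991 per array, and that with arrays of the same group averaged 0.751 to 0.975. A gene was taken as above background in a group where its signal was at least 1.5 times background in the strain's channel on an array. Genes below that on every array of a group stayed in the fit and the test. In the list counts, measured members are those that the array holds, whatever their signal.

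All 57 arrays entered 1 limma model (lmFit and eBayes) with a coefficient per group, a dye term and a reference pool term. It had 20 residual degrees of freedom, and eBayes added 3.73 with a prior SD of 0.0769. Changes are contrasts of group coefficients, and p-values are two-sided and adjusted by Benjamini and Hochberg over the 5311 genes of each comparison. For strains with 1 array the spread comes from the other groups. In the rpb1 wild type (URA3) dye and pool went together: arrays 1 and 2 were in Cy3 with pool 3, arrays 3 and 4 in Cy5 with pool 1. Arrays in Cy3 with pool 1 or in Cy5 with pool 3 thus have no rpb1 wild-type (URA3) array of their kind. Their comparisons rely on dye and pool terms that add up and are estimated with the help of other groups. The rpb7 strains got values with no test, since both have 1 array. Correlations between comparisons are across genes and were not tested.

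Gene lists fixed in advance, 23 in all, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists of a comparison. They held a-specific, α-specific and pheromone response genes, GTP and pyrimidine genes, and genes of the phosphate, iron, amino acid (Gcn4), sulfur, purine, galactose, ergosterol, stress (Msn2 and Msn4) and chaperone (Hsf1) programmes. They also held ribosome biogenesis, ribosomal protein, glycolysis, hexose transport, respiratory chain, histone, proteasome, RNA polymerase II, PAU and COS genes.

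Genes were named by a rule set before the data were examined. For the main comparisons it took up to 8 genes that rose and 8 that fell with the largest changes past the threshold, where all arrays lay on the same side of the wild-type mean. For fast against slow, every allele of one class had to lie on the same side of the other, and interactions had no such condition. It added 4 members of at most 5 called lists. For other alleles it took up to 3 in each direction, and it allowed plasmid marker genes, subunit genes, IMD2, SUB1 and mating-type genes everywhere. Within the choices the rule gave, the text shows a part, and all are counted in the closing section.

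The test was tried on simulated data, with 200 of 5311 genes changed and noise drawn independently for each gene. For E1103G (URA3), 79.7% of genes changed 1.3-fold, 93.2% of those changed 1.5-fold and 100% of those changed 2-fold were recovered, and 4.19% of calls were false. For E1103G (LEU2) the values were 78.8%, 95.9%, 100% and 6.63%. For the deletion of SUB1 in the wild type they were 77.0%, 94.8%, 98.5% and 5.29%, and for N445Y (1 array) 66.2%, 86.4%, 98.4% and 2.92%. A proteasome list shifted 1.3-fold for E1103G (URA3) was called by camera, with 1 other list of the 23.

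Alternatives were median centring, print-tip loess (48 blocks, span 0.4), no background correction, the authors' log2 ratios, no dye term, no pool term, only arrays of the same subunit and marker, only pool 3 arrays of the LEU2 set, no dimmest 25 percent of genes, and a threshold that also asks for a change over 1.7-fold. Each array of the compared groups was also left out in turn. Slide or scan date as a block was not run, since the files give neither. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.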

Results

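Gene expression was measured in budding yeast strains that carried point mutations in RNA polymerase II, the enzyme that transcribes protein-coding genes. The 57 arrays held 35 groups: strains with mutations in RPB1 (gene name RPO21), RPB2 or RPB7, their wild types, and strains in which SUB1, a gene for a transcription coactivator, was deleted. The mutated gene sat on a plasmid with a URA3 marker or, in 4 groups, a LEU2 marker, per the labels. Of the groups, 17 had 2 or more arrays and 18 had 1. Each array compared 1 strain with a common reference RNA on the same glass slide, and replicates were separate cultures per the study design, hybridised with the dyes swapped. In N479A and F1086S the labels name the strain sample of both arrays alike but for the letter that goes with the dye, so they show no second isolate, and 2 of the 3 N479S arrays are of 1 isolate.

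Signal stood well above the local background. The median brightness of a gene was between 192 and 561 in the Cy5 channel and between 132 and 444 in the Cy3 channel, over median backgrounds of 50 to 64 and 38 to 47. Between 86.6% and 97.4% of the genes were above background on an array, and the number of arrays limits the precision. No array pair within a group was identical. Changes are given below as log2 of the strain over its wild type ± the standard error from limma, for 5311 genes, and a gene is said to have risen or fallen where its Benjamini-Hochberg adjusted p was below 0.05. Genes named for their size had every array of the mutant on the same side of the wild-type mean.

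The URA3 and LEU2 strain sets differed in mating type mRNAs. In the LEU2 wild type, STE2, the α-factor receptor of a cells, lay 4.31 ± 0.26 above the reference on the log2 scale (SD, n = 3), and MF(ALPHA)1, the main α-factor pheromone gene, lay at -5.62 ± 0.50. In the URA3 wild type STE2 was at 0.03 ± 0.04 and MF(ALPHA)1 at 0.15 ± 0.09 (SD, n = 4). The LEU2 strains therefore carried the mRNAs of a cells, and the URA3 strains carried those of α cells like the reference.

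**Figure D1:**
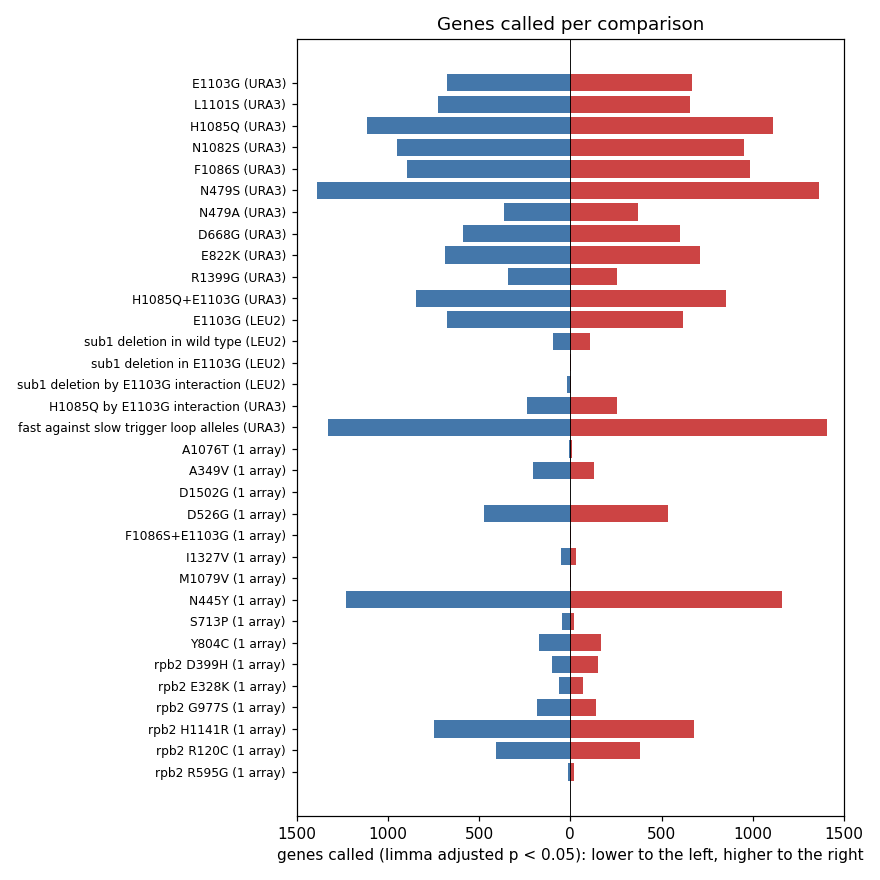
Number of genes called higher (red, right) and lower (blue, left) in each comparison by limma at an adjusted p below 0.05, with 1 bar pair per comparison. N479S has 1361 higher and 1387 lower genes, and the deletion of SUB1 in E1103G has 1 and 2.

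E1103G lies in the trigger loop of Rpb1 and is known to speed elongation. In the E1103G strain (URA3), SER3, the first enzyme of serine synthesis, rose by 2.45 ± 0.16, which is 5.46-fold. The ammonium permease MEP2 rose by 1.68 ± 0.20, the urea transporter DUR3 by 1.40 ± 0.16, the allantoin-degrading DAL3 by 1.08 ± 0.14 and the amino acid permease GAP1 by 0.88 ± 0.20. The α-pheromone gene MF(ALPHA)2 fell by 2.94 ± 0.24, the α-agglutinin SAG1 by 1.60 ± 0.14, the a-factor receptor STE3 by 1.09 ± 0.12 and PRM7, a pheromone-regulated membrane protein, by 1.51 ± 0.18. IMD2, an IMP dehydrogenase of GTP synthesis, fell by 0.82 ± 0.16 and the hexokinase HXK1 by 1.32 ± 0.30. In all, 666 genes rose and 674 fell, with n = 2 against 4, and of those changed over 1.7-fold 15 rose and 58 fell. The count was 776 with median centring in place of loess, 869 without the dye term, 345 higher and 426 lower without the pool term, 512 without E1103G (URA3) array 1 and 619 without E1103G (URA3) array 2. GAP1 lost its call without E1103G (URA3) array 1 (adjusted p = 0.0553). HXK1 lost its call without E1103G (URA3) array 1 (log2 change -0.83, adjusted p = 0.174).

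Among gene groups in the same strain, subunits of the proteasome moved up: 12 of 32 measured members rose and 20 did not pass the test (13 higher adjusted over the list alone), with a camera adjusted p = 4.14e-05 and adjusted p = 0.47 with an estimated correlation. PUP2 rose by 0.41 ± 0.08 and PUP1 by 0.38 ± 0.07. Among glycolytic genes, 8 of 16 measured members fell and 8 did not pass the test (8 lower adjusted over the list alone), with a camera adjusted p = 0.000498 and adjusted p = 0.515 with an estimated correlation. The triosephosphate isomerase TPI1 fell by 1.09 ± 0.13, the phosphoglucose isomerase PGI1 by 0.63 ± 0.09 and the phosphoglycerate mutase GPM1 by 0.46 ± 0.09. Among pheromone response genes, 1 of 16 measured members rose, 9 fell and 6 did not pass the test (1 higher and 9 lower adjusted over the list alone), with a camera adjusted p = 0.000357 and adjusted p = 0.0996 with an estimated correlation. FAR1, which arrests the cell cycle during mating, fell by 1.16 ± 0.07. Among α-specific genes, 3 of 4 measured members fell and 1 did not pass the test (3 lower adjusted over the list alone), with a camera adjusted p = 4.14e-05 and adjusted p = 0.0996 with an estimated correlation, and the gene that did not pass was MF(ALPHA)1. Among genes of the phosphate regulon, 3 of 11 measured members rose and 8 did not pass the test (4 higher adjusted over the list alone), with a camera adjusted p = 0.103. GPM1 lost its call with print-tip loess (log2 change 0.47, adjusted p = 0.0819) and in the authors' deposited values (0.66).

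E1103G on the LEU2 plasmid was compared with the LEU2 wild type (n = 3 against 3). SER3 rose by 1.79 ± 0.15, the spliceosome component DIB1 by 0.98 ± 0.07, the purine enzyme ADE17 by 0.85 ± 0.20 and the glutamate dehydrogenase GDH1 by 0.82 ± 0.10. The serine deaminase CHA1 fell by 1.76 ± 0.09, HXK1 by 1.35 ± 0.28, FAR1 by 1.24 ± 0.07, the glycolytic activator TYE7 by 1.11 ± 0.13 and the purine salvage enzyme HPT1 by 1.10 ± 0.09. IMD2 fell by 0.75 ± 0.15. In this set 1296 genes passed the test, 620 of them higher, and of those changed over 1.7-fold 10 rose and 38 fell. The count was 661 with median centring in place of loess (229 higher and 432 lower), 767 without the pool term and 784 from only the arrays of the same subunit and marker.

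In these a cells the a-specific genes moved down: 6 of 7 measured members fell and 1 did not pass the test (6 lower adjusted over the list alone), with a camera adjusted p = 4.95e-07 and adjusted p = 0.156 with an estimated correlation. STE2 fell by 0.89 ± 0.11, the agglutinin subunit AGA2 by 0.82 ± 0.07 and the protease BAR1 by 0.46 ± 0.08. Among α-specific genes, 1 of 4 measured members rose and 3 did not pass the test (1 higher adjusted over the list alone), with a camera adjusted p = 0.362. Respiratory chain genes included CYC1, higher by 0.69 ± 0.16, and 6 of 33 measured members rose and 27 did not pass the test (6 higher adjusted over the list alone), with a camera adjusted p = 0.000141 and adjusted p = 0.673 with an estimated correlation. Among pheromone response genes, 1 of 16 measured members rose, 9 fell and 6 did not pass the test (1 higher and 9 lower adjusted over the list alone), with a camera adjusted p = 0.00128 and adjusted p = 0.156 with an estimated correlation. Among hexose transporters, 1 of 7 measured members rose and 6 did not pass the test (0 adjusted over the list alone), with a camera adjusted p = 0.203. The respiratory chain list lost its call without wild-type (LEU2) array 3 (adjusted p = 0.118).

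Across genes, the E1103G changes of both strain sets correlated at r = 0.775, over independent controls, and the 6 pairings of single mutant arrays gave 0.671 to 0.729. Genes are not independent replicates. The r was 0.743 without E1103G (LEU2) array 1, 0.728 without E1103G (URA3) array 2, 0.655 without wild-type (LEU2) array 2 and 0.815 without array 3. Of the called genes, 385 were higher in both sets and 432 lower in both, where independent lists would share 77.8 and 85.8, and 3 went opposite ways. H1085Q against the same LEU2 profile gave r = 0.347, with pairings from 0.162 to 0.484. The difference of both E1103G effects, tested as a contrast after the mating types were seen, called 13 genes. Among them were MF(ALPHA)2 at 2.93 ± 0.33, SAG1 at 1.79 ± 0.19, STE2 at -0.74 ± 0.16 and AGA2 at -0.83 ± 0.10 for LEU2 minus URA3. Each of these genes is specific to 1 mating type. In cells of the other type its mRNA has little room to fall. For them the contrast cannot tell mating type apart from an E1103G effect that differs. STE2 lost its call with median centring in place of loess (adjusted p = 0.0682), without the dye term (0.0636), without the pool term (0.0765), from only the arrays of the same subunit and marker (0.0524) and on leaving out E1103G (LEU2) array 1 (0.146), E1103G (URA3) array 1 (0.183), wild-type (LEU2) array 2 (0.0689), wild-type (URA3) array 1 (0.0692), wild-type (URA3) array 2 (0.102), E1103G (LEU2) array 3 (0.0848), wild-type (LEU2) array 3 (0.175), E1103G (URA3) array 2 (0.374), wild-type (URA3) array 3 (0.0849) or wild-type (URA3) array 4 (0.075).

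**Figure D2:**
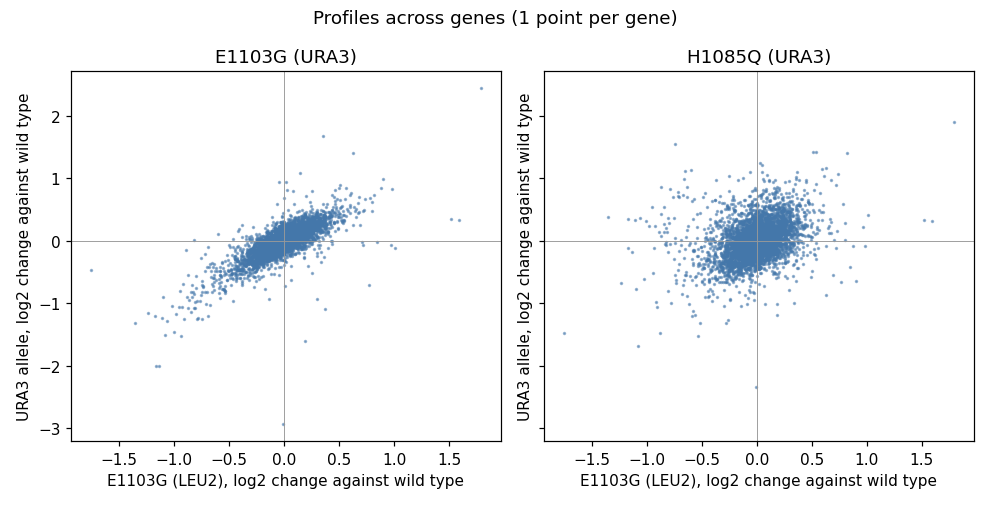
Log2 change of each gene in E1103G (URA3, left) and H1085Q (URA3, right) against its change in E1103G (LEU2), each over its own wild type, with 1 point per gene. The left cloud follows the diagonal (r = 0.775) more closely than the right (r = 0.347).

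L1101S, another fast trigger loop allele, raised MEP2 by 1.75 ± 0.20 and SER3 by 1.45 ± 0.16 (n = 2 against 4). MF(ALPHA)2 fell by 2.51 ± 0.24 and the membrane protein gene YRO2 by 2.16 ± 0.28, and IMD2 fell by 0.54 ± 0.16. Subunits of the proteasome moved up: 12 of 32 measured members rose and 20 did not pass the test (16 higher adjusted over the list alone), with a camera adjusted p = 1.41e-05 and adjusted p = 0.356 with an estimated correlation. Among genes of the general stress regulon of Msn2 and Msn4, 6 of 24 measured members fell and 18 did not pass the test (6 lower adjusted over the list alone), with a camera adjusted p = 0.00462 and adjusted p = 0.894 with an estimated correlation. Among genes for RNA polymerase II subunits, 4 of 12 measured members rose and 8 did not pass the test (4 higher adjusted over the list alone), with a camera adjusted p = 0.0105 and adjusted p = 0.356 with an estimated correlation. The test called 656 genes higher and 723 lower, and of those changed over 1.7-fold 16 rose and 49 fell. The count was 870 with median centring in place of loess, 828 without the pool term and 386 without L1101S (URA3) array 2. The pol2 subunits list lost its call with median centring in place of loess (adjusted p = 0.0743) and without L1101S (URA3) array 2 (0.171). IMD2 lost its call without L1101S (URA3) array 2 (adjusted p = 0.179). The stress list lost its call without L1101S (URA3) array 2 (adjusted p = 0.193).

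H1085Q replaces the trigger loop histidine and is known to slow elongation. SER3 rose by 1.91 ± 0.16, IMD2 by 1.55 ± 0.16, the small chaperone HSP42 by 1.42 ± 0.31, GAP1 by 1.42 ± 0.20 and GDH1 by 1.41 ± 0.10 (n = 2 against 4). MF(ALPHA)2 fell by 2.35 ± 0.24, PRM7 by 1.69 ± 0.18, the bromodomain gene BDF2 by 1.52 ± 0.09, CHA1 by 1.47 ± 0.10, the RNA helicase DBP2 by 1.31 ± 0.23 and the branched-chain enzyme ILV5 by 1.27 ± 0.13. The subtelomeric helicases YRF1-7 and YRF1-5 rose by 1.24 ± 0.15 and 1.21 ± 0.17, and are uncertain because near-identical copies can hybridise to 1 probe. The test called 1111 genes higher and 1116 lower. The count was 1275 without H1085Q (URA3) array 1.

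Several groups moved in H1085Q. Among genes of GTP and pyrimidine synthesis, 5 of 6 measured members rose and 1 did not pass the test (5 higher adjusted over the list alone), with a camera adjusted p = 4.16e-05 and adjusted p = 0.106 with an estimated correlation. URA2, the first enzyme of pyrimidine synthesis, rose by 1.04 ± 0.09, IMD3 by 1.11 ± 0.12 and IMD4 by 1.13 ± 0.13. Among ribosome biogenesis genes, 32 of 49 measured members fell and 17 did not pass the test (33 lower adjusted over the list alone), with a camera adjusted p = 5.07e-08 and adjusted p = 0.681 with an estimated correlation. The GTPase gene NOG2 fell by 0.79 ± 0.13 and the export adaptor NMD3 by 0.72 ± 0.12. Among chaperone genes of Hsf1, 14 of 19 measured members rose and 5 did not pass the test (15 higher adjusted over the list alone), with a camera adjusted p = 1.45e-05 and adjusted p = 0.583 with an estimated correlation, with SIS1 higher by 0.84 ± 0.15 and HSC82 by 0.81 ± 0.10. Among stress genes of Msn2 and Msn4, 13 of 24 measured members rose and 11 did not pass the test (13 higher adjusted over the list alone), with a camera adjusted p = 0.000323 and adjusted p = 0.714 with an estimated correlation. Among PAU cell wall genes, whose copies are near-identical, 16 of 16 measured members rose (16 higher adjusted over the list alone), with a camera adjusted p = 5.69e-10 and adjusted p = 0.402 with an estimated correlation. Among histone genes, 5 of 10 measured members fell and 5 did not pass the test (5 lower adjusted over the list alone), with a camera adjusted p = 0.0103 and adjusted p = 0.613 with an estimated correlation. The histones list lost its call with print-tip loess (adjusted p = 0.0566), in the authors' deposited values (0.0594) and without H1085Q (URA3) array 2 (0.113). The stress list lost its call without H1085Q (URA3) array 1 (adjusted p = 0.113).

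N1082S and F1086S are also slow trigger loop alleles. In N1082S, IMD2 rose by 1.67 ± 0.16, SER3 by 1.34 ± 0.16 and GDH1 by 1.23 ± 0.10, while MF(ALPHA)2 fell by 2.65 ± 0.24 and PRM7 by 1.67 ± 0.18 (n = 2 against 4). Ribosome biogenesis genes moved down: 28 of 49 measured members fell and 21 did not pass the test (29 lower adjusted over the list alone), with a camera adjusted p = 3.71e-08 and adjusted p = 0.661 with an estimated correlation. Chaperone genes moved up: 15 of 19 measured members rose and 4 did not pass the test (15 higher adjusted over the list alone), with a camera adjusted p = 3.14e-06 and adjusted p = 0.487 with an estimated correlation. The test called 954 genes higher and 951 lower. The count was 1201 without the pool term and 493 without N1082S (URA3) array 2.

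In F1086S, IMD2 rose by 1.71 ± 0.16, SER3 by 1.47 ± 0.17 and GDH1 by 1.43 ± 0.11, while MF(ALPHA)2 fell by 2.13 ± 0.25, PRM7 by 1.83 ± 0.18 and CHA1 by 1.33 ± 0.10 (n = 2 against 4). Among respiratory chain genes, 13 of 33 measured members rose and 20 did not pass the test (13 higher adjusted over the list alone), with a camera adjusted p = 0.000145 and adjusted p = 0.721 with an estimated correlation. Among purine synthesis genes, 5 of 10 measured members fell and 5 did not pass the test (6 lower adjusted over the list alone), with a camera adjusted p = 0.0368 and adjusted p = 0.655 with an estimated correlation. The test called 983 genes higher and 896 lower. The count was 844 without F1086S (URA3) array 1 and 1107 without F1086S (URA3) array 2. The purine synthesis list lost its call from only the arrays of the same subunit and marker (adjusted p = 0.065) and on leaving out F1086S (URA3) array 2 (0.0884) or wild-type (URA3) array 1 (0.0731).

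**Figure D3:**
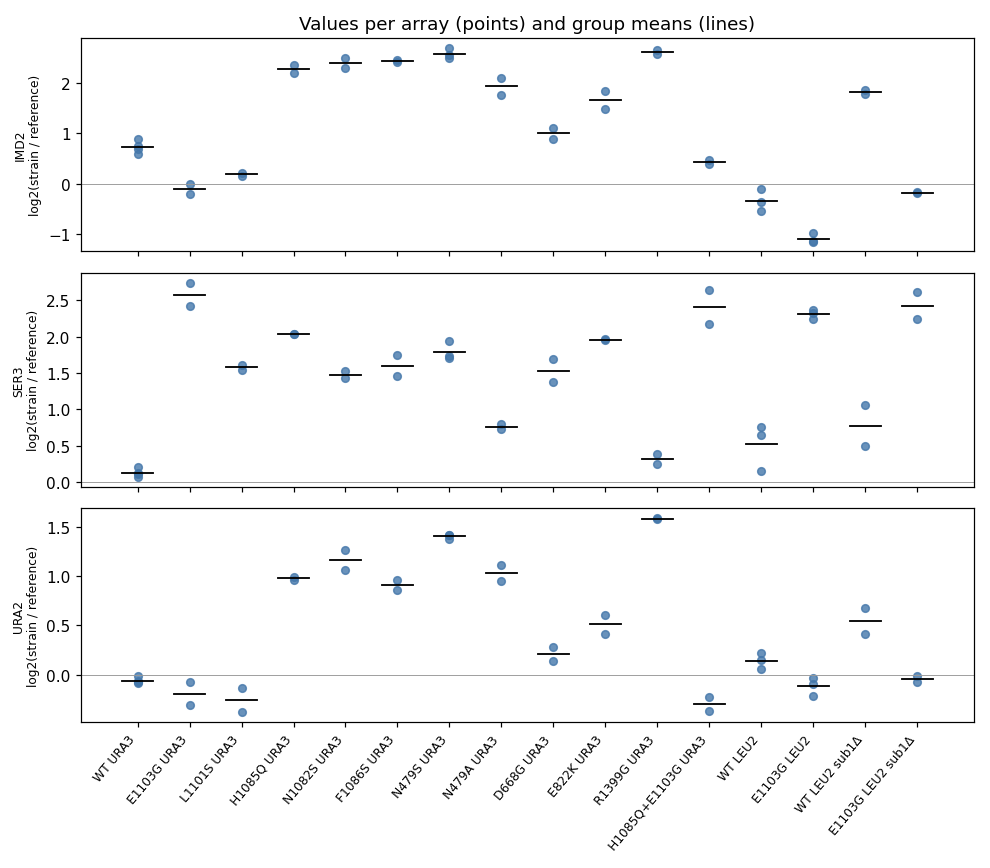
Log2 of strain over reference for IMD2, SER3 and URA2 on each array (points), adjusted for dye and reference pool, with group means (lines). IMD2 was lower than wild type in E1103G (-0.82) and higher in H1085Q (1.55), while SER3 was higher in both (2.45 and 1.91).

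The fast alleles (E1103G and L1101S) were set against the slow alleles (H1085Q, N1082S and F1086S), classes fixed before the data were examined. The IMP dehydrogenases IMD2, IMD3 and IMD4 were lower in the fast class, with log2 differences of -2.32 ± 0.12, -1.91 ± 0.09 and -1.74 ± 0.10, as were the heat shock gene HSP12 at -1.81 ± 0.25 and URA2 at -1.24 ± 0.06. Cross-hybridisation among the related IMD genes was not tested, here or in other comparisons, so their changes may not be separate. URA2 was at -0.51 with print-tip loess and at -0.81 in the authors' deposited values. The flavohemoglobin YHB1 was higher by 1.26 ± 0.13, the arginine gene ARG1 by 1.08 ± 0.25, DBP2 by 1.01 ± 0.17 and the acid phosphatase PHO3 by 0.97 ± 0.08. The test called 1405 genes higher in the fast class and 1328 lower (4 against 6 arrays), and of those changed over 1.7-fold 23 were higher and 100 lower. Its spread is that between arrays of the same strain, not between alleles of a class. The calls therefore hold for these alleles and not for fast and slow alleles in general. With the arrays pooled by class the count was 2754, against 1503 in the highest other split of whole alleles. Among Msn2 and Msn4 stress genes, 22 of 24 measured members fell and 2 did not pass the test (23 lower adjusted over the list alone), with a camera adjusted p = 4.46e-08 and adjusted p = 0.64 with an estimated correlation. Among ribosome biogenesis genes, 38 of 49 measured members rose and 11 did not pass the test (38 higher adjusted over the list alone), with a camera adjusted p = 3.47e-07 and adjusted p = 0.64 with an estimated correlation. Among ribosomal protein genes, 44 of 120 measured members rose, 6 fell and 70 did not pass the test (44 higher and 6 lower adjusted over the list alone), with a camera adjusted p = 0.00348 and adjusted p = 0.709 with an estimated correlation. Among the GTP and pyrimidine genes, 5 of 6 measured members fell and 1 did not pass the test (5 lower adjusted over the list alone), with a camera adjusted p = 2.05e-05 and adjusted p = 0.17 with an estimated correlation. The Ty1 open reading frames YDR210C-C and YPR158W-A were lower at -2.12 ± 0.22 and -2.06 ± 0.20, and are uncertain because near-identical copies can share a probe. The ribosomal protein list lost its call in the authors' deposited values (adjusted p = 0.458) and without E1103G (URA3) array 2 (0.0501).

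N479 lies near the active site. In N479S (n = 3 against 4) IMD2 rose by 1.86 ± 0.14, SER3 by 1.66 ± 0.15 and GAP1 by 1.53 ± 0.18, while MF(ALPHA)2 fell by 2.16 ± 0.21, PRM7 by 1.83 ± 0.16 and the multidrug transporter AQR1 by 1.68 ± 0.15. Among chaperone genes, 15 of 19 measured members rose and 4 did not pass the test (16 higher adjusted over the list alone), with a camera adjusted p = 5.26e-06 and adjusted p = 0.517 with an estimated correlation. Among ribosome biogenesis genes, 34 of 49 measured members fell and 15 did not pass the test (35 lower adjusted over the list alone), with a camera adjusted p = 9.78e-08 and adjusted p = 0.702 with an estimated correlation. Among PAU genes, 16 of 16 measured members rose (16 higher adjusted over the list alone), with a camera adjusted p = 5.5e-08 and adjusted p = 0.517 with an estimated correlation. The test called 1361 genes higher and 1387 lower.

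In N479A (n = 2 against 4) IMD2 rose by 1.21 ± 0.16, URA2 by 1.09 ± 0.09 and HSP42 by 1.08 ± 0.31, while PRM7 fell by 1.62 ± 0.18 and DBP2 by 0.90 ± 0.23. Among the GTP and pyrimidine genes, 4 of 6 measured members rose and 2 did not pass the test (5 higher adjusted over the list alone), with a camera adjusted p = 2.1e-06 and adjusted p = 0.0722 with an estimated correlation. The α-specific genes did not pass: 0 of 4 measured members passed the test (0 adjusted over the list alone), with a camera adjusted p = 0.337. The test called 371 genes higher and 364 lower. The count was 413 with median centring in place of loess, 421 without the dye term, 313 without the pool term, 478 without wild-type (URA3) array 1, 460 without wild-type (URA3) array 2 and 90 without N479A (URA3) array 2. HSP42 lost its call without the pool term (adjusted p = 0.0689) and on leaving out N479A (URA3) array 2 (log2 change 0.64, 0.483) or wild-type (URA3) array 3 (0.0575). DBP2 lost its call without N479A (URA3) array 2 (log2 change -0.48, adjusted p = 0.443).

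In D668G (n = 2 against 4) MEP2 rose by 1.62 ± 0.20, DUR3 by 1.59 ± 0.16 and the mitochondrial chaperone HSP78 by 1.40 ± 0.22, while MF(ALPHA)2 fell by 2.61 ± 0.24, PRM7 by 1.40 ± 0.18 and the transporter NRT1 by 1.38 ± 0.11. Among chaperone genes, 12 of 19 measured members rose and 7 did not pass the test (16 higher adjusted over the list alone), with a camera adjusted p = 2.77e-07 and adjusted p = 0.539 with an estimated correlation. Among ergosterol genes, 4 of 22 measured members fell and 18 did not pass the test (6 lower adjusted over the list alone), with a camera adjusted p = 0.0176 and adjusted p = 0.539 with an estimated correlation. The test called 1189 genes, 50.6% of them higher. The count was 697 with median centring in place of loess, 686 without the dye term, 569 without the pool term and 320 without D668G (URA3) array 1. The ergosterol list lost its call in the authors' deposited values (adjusted p = 0.211).

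In E822K (n = 2 against 4) SER3 rose by 1.83 ± 0.16, GDH1 by 1.42 ± 0.10 and GAP1 by 1.35 ± 0.20, while MF(ALPHA)2 fell by 3.09 ± 0.24 and PRM7 by 1.56 ± 0.18. Among ribosome biogenesis genes, 23 of 49 measured members fell and 26 did not pass the test (29 lower adjusted over the list alone), with a camera adjusted p = 1.35e-08 and adjusted p = 0.745 with an estimated correlation. Among amino acid genes of Gcn4, 4 of 25 measured members rose and 21 did not pass the test (4 higher adjusted over the list alone), with a camera adjusted p = 0.507 (median -0.05 and mean 0.01), among sulfur genes 6 of 22 measured members rose, 4 fell and 12 did not pass the test (8 higher and 4 lower adjusted over the list alone), with a camera adjusted p = 0.292, and among galactose genes 1 of 6 measured members fell and 5 did not pass the test (0 adjusted over the list alone), with a camera adjusted p = 0.847. The test called 1397 genes, 712 of them higher. The count was 909 with median centring in place of loess (370 higher and 539 lower), 8.0e2 without the pool term and 544 without E822K (URA3) array 1.

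In R1399G (n = 2 against 4) IMD2 rose by 1.89 ± 0.16, URA2 by 1.64 ± 0.09 and IMD3 by 1.34 ± 0.12, while the siderophore mannoprotein FIT2 fell by 1.11 ± 0.18, the peroxisomal citrate synthase CIT2 by 1.10 ± 0.23 and the biotin gene BIO5 by 1.07 ± 0.13. Among the GTP and pyrimidine genes, 5 of 6 measured members rose and 1 did not pass the test (5 higher adjusted over the list alone), with a camera adjusted p = 7.22e-13 and adjusted p = 0.00203 with an estimated correlation. Among genes of the iron regulon, 11 of 16 measured members fell and 5 did not pass the test (11 lower adjusted over the list alone), with a camera adjusted p = 3.81e-11 and adjusted p = 0.0479 with an estimated correlation. Among subtelomeric COS genes, whose copies are near-identical, 2 of 10 measured members fell and 8 did not pass the test (2 lower adjusted over the list alone), with a camera adjusted p = 0.395. The test called 258 genes higher and 344 lower. The count was 354 with median centring in place of loess (97 higher and 257 lower), 293 without the dye term, 345 without the pool term, 253 without R1399G (URA3) array 1 and 121 without R1399G (URA3) array 2. CIT2 lost its call without R1399G (URA3) array 2 (adjusted p = 0.0834).

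H1085Q and E1103G were also combined in 1 strain, which asks whether the slow and the fast change offset each other. In the double mutant (n = 2 against 4) MEP2 rose by 2.43 ± 0.20, SER3 by 2.28 ± 0.16 and DUR3 by 1.85 ± 0.16, while MF(ALPHA)2 fell by 2.25 ± 0.24, PRM7 by 1.88 ± 0.18 and SAG1 by 1.53 ± 0.14. IMD2 was at -0.30 and did not pass the test. Proteasome genes moved up: 21 of 32 measured members rose and 11 did not pass the test (22 higher adjusted over the list alone), with a camera adjusted p = 5.88e-07 and adjusted p = 0.333 with an estimated correlation. Among ribosome biogenesis genes, 34 of 49 measured members fell and 15 did not pass the test (36 lower adjusted over the list alone), with a camera adjusted p = 9.23e-11 and adjusted p = 0.663 with an estimated correlation. Among pheromone response genes, 10 of 16 measured members fell and 6 did not pass the test (10 lower adjusted over the list alone), with a camera adjusted p = 2.88e-06 and adjusted p = 0.0223 with an estimated correlation. The test called 852 genes higher and 846 lower. The count was 1120 with median centring in place of loess, 1040 without the pool term, 784 without H1085Q+E1103G (URA3) array 1 and 1112 without H1085Q+E1103G (URA3) array 2.

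The interaction tested whether the double mutant differed from the sum of both single changes. It was positive for MF(ALPHA)2 (3.04 ± 0.37), the cell wall gene CWP1 (1.69 ± 0.23), the permease BAP2 (1.35 ± 0.21), SAG1 (1.26 ± 0.21) and STE3 (0.93 ± 0.18). It was negative for SER3 (-2.08 ± 0.25), URA2 (-1.14 ± 0.13), IMD2 (-1.03 ± 0.24), RPO21 (-1.15 ± 0.22) and the acetyltransferase ATF1 (-1.01 ± 0.18). The test called 492 genes, 256 positive and 236 negative. A change of like size in both single mutants and the double, as for MF(ALPHA)2 and SER3, gives an interaction of opposite sign by itself. Among PAU genes, 14 of 16 measured members fell and 2 did not pass the test (16 lower adjusted over the list alone), with a camera adjusted p = 4.16e-15 and adjusted p = 0.168 with an estimated correlation, where fell means a negative interaction. Among α-specific genes, 3 of 4 measured members rose and 1 did not pass the test (3 higher adjusted over the list alone), with a camera adjusted p = 0.000198 and adjusted p = 0.168 with an estimated correlation. The count was 270 with median centring in place of loess, 253 without the dye term, 241 without the pool term, 192 without E1103G (URA3) array 1, 257 without H1085Q (URA3) array 1, 197 without H1085Q+E1103G (URA3) array 1, 282 without E1103G (URA3) array 2 and 276 without H1085Q (URA3) array 2. IMD2 lost its call with print-tip loess (log2 change -0.58, adjusted p = 0.153) and on leaving out E1103G (URA3) array 1 (0.0739), H1085Q (URA3) array 1 (0.0532) or H1085Q+E1103G (URA3) array 1 (0.0518).

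SUB1 was deleted in the LEU2 strains. The SUB1 signal fell by 2.39 ± 0.10 in the wild type and fell by 2.61 ± 0.10 in E1103G. On array 1 of the sub1-deleted wild type the reference channel held URA3 signal at 23 times background, against 1.08 to 1.30 on the other 9 LEU2 arrays, while the strain channel was at 2.24. The log2 ratio change of URA3 in this comparison was -1.95, and it was -0.31 (adjusted p = 0.662) without the array. Counts and lists are therefore also given without array 1, an alternative chosen after seeing the data. That leaves 1 array of the sub1-deleted wild type, which is assumed to vary like the other groups.

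In the wild type (n = 2 against 3), deletion of SUB1 raised IMD2 by 2.15 ± 0.17, IMD3 by 1.29 ± 0.13 and IMD4 by 1.09 ± 0.14, the a-agglutinin anchor AGA1 by 1.46 ± 0.14 and the mating gene FIG1 by 1.28 ± 0.06. The siderophore transporter SIT1 fell by 1.14 ± 0.15. IMD2 (2.11), IMD3 (1.29), AGA1 (1.29), FIG1 (1.16) and SIT1 (-1.10) kept their calls without array 1. The heat shock gene HSP12 fell by 1.29 ± 0.36 and CHA1 by 0.94 ± 0.10. The test called 107 genes higher and 96 lower, and 35 (21 higher and 14 lower) without array 1. The count was 152 with median centring in place of loess (43 higher and 109 lower), 109 without the dye term, 72 without the pool term, 56 from only the arrays of the same subunit and marker, 135 with only the pool 3 LEU2 arrays, 125 without wild-type (LEU2) array 1, 556 without wild-type (LEU2) array 2, 35 without sub1-deleted wild-type array 1 and 83 without wild-type (LEU2) array 3. HSP12 lost its call without the dye term (adjusted p = 0.0758), without the pool term (0.135), from only the arrays of the same subunit and marker (0.127), with only the pool 3 LEU2 arrays (0.0994) and on leaving out wild-type (LEU2) array 1 (0.148), sub1-deleted wild-type array 1 (0.447), wild-type (LEU2) array 3 (0.153) or sub1-deleted wild-type array 2 (0.0781).

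Among pheromone response genes, 11 of 16 measured members rose and 5 did not pass the test (14 higher adjusted over the list alone), with a camera adjusted p = 6.41e-35 and adjusted p = 1.38e-07 with an estimated correlation. Without array 1, 8 rose with a median of 0.51 and adjusted p = 9.19e-08 with an estimated correlation. Among a-specific genes, 6 of 7 measured members rose and 1 did not pass the test (7 higher adjusted over the list alone), with a camera adjusted p = 5.98e-16 and adjusted p = 0.00469 with an estimated correlation, and 3 rose without array 1. AGA2 rose by 0.87 ± 0.08, ASG7 by 0.87 ± 0.07 and BAR1 by 0.67 ± 0.09. Markers of α cells moved with them: 1 of 4 measured members rose and 3 did not pass the test (4 higher adjusted over the list alone), with a camera adjusted p = 0.00223 and adjusted p = 0.15 with an estimated correlation. MF(ALPHA)1 was higher by 0.71 ± 0.20, and without array 1 the median of the 4 α-specific genes was 0.14 with 0 called (camera adjusted p = 0.185). MF(ALPHA)1 lost its call without the dye term (adjusted p = 0.0544), without the pool term (0.0863), from only the arrays of the same subunit and marker (0.302), with only the pool 3 LEU2 arrays (0.0724) and on leaving out wild-type (LEU2) array 1 (0.0783), wild-type (LEU2) array 2 (log2 change 0.43, 0.117) or sub1-deleted wild-type array 1 (0.588). The alpha specific list lost its call without sub1-deleted wild-type array 1 (adjusted p = 0.185).

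Among genes of GTP and pyrimidine synthesis, 4 of 6 measured members rose and 2 did not pass the test (4 higher adjusted over the list alone), with a camera adjusted p = 6.27e-12 and adjusted p = 0.00194 with an estimated correlation, and 3 rose without array 1. Among iron regulon genes, 8 of 16 measured members fell and 8 did not pass the test (11 lower adjusted over the list alone), with a camera adjusted p = 2.39e-11 and adjusted p = 0.0223 with an estimated correlation, with FET3 at -0.89 ± 0.16, FRE1 at -0.74 ± 0.11 and ARN1 at -0.75 ± 0.12, and 4 fell without array 1. Among histone genes, 6 of 10 measured members fell and 4 did not pass the test (9 lower adjusted over the list alone), with a camera adjusted p = 3.42e-09 and adjusted p = 0.0223 with an estimated correlation. Without array 1 the histone median was -0.22 with 0 called, and adjusted p = 0.0683 with an estimated correlation. The α-specific median over both arrays was 0.48. FRE1 lost its call without the pool term (adjusted p = 0.0685). FET3 lost its call without the pool term (adjusted p = 0.0548).

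In E1103G, deletion of SUB1 called 3 genes (n = 2 against 3), by limma, with 252 at an unadjusted p below 0.05. IMD2 rose by 0.91 ± 0.17, SUB1 fell, and CHA1 fell by 0.63 ± 0.10. Among purine synthesis genes, 0 of 10 measured members passed the test (7 higher adjusted over the list alone), with a camera adjusted p = 5.48e-12 and adjusted p = 0.0382 with an estimated correlation. Among pheromone response genes, 0 of 16 measured members passed the test (0 adjusted over the list alone), with a camera adjusted p = 0.013 and adjusted p = 0.323 with an estimated correlation. Among the GTP and pyrimidine genes, 1 of 6 measured members rose and 5 did not pass the test (3 higher adjusted over the list alone), with a camera adjusted p = 6.97e-06 and adjusted p = 0.0505 with an estimated correlation. The count was 2 with median centring in place of loess (1 higher and 1 lower), 1 without the dye term and 1 without sub1-deleted E1103G array 1. CHA1 lost its call with median centring in place of loess (adjusted p = 0.191), without the dye term (0.0587), without the pool term (0.137), from only the arrays of the same subunit and marker (0.499) and without sub1-deleted E1103G array 1 (0.998). The pheromone response list lost its call with median centring in place of loess (adjusted p = 0.671), without the pool term (0.0532), without the dimmest 25 percent of genes (0.0503) and on leaving out E1103G (LEU2) array 2 (0.0655) or sub1-deleted E1103G array 2 (0.142). IMD2 lost its call without the dye term (adjusted p = 0.0529) and on leaving out E1103G (LEU2) array 2 (0.147), sub1-deleted E1103G array 1 (0.998), E1103G (LEU2) array 3 (0.113) or sub1-deleted E1103G array 2 (0.411).

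**Figure D4:**
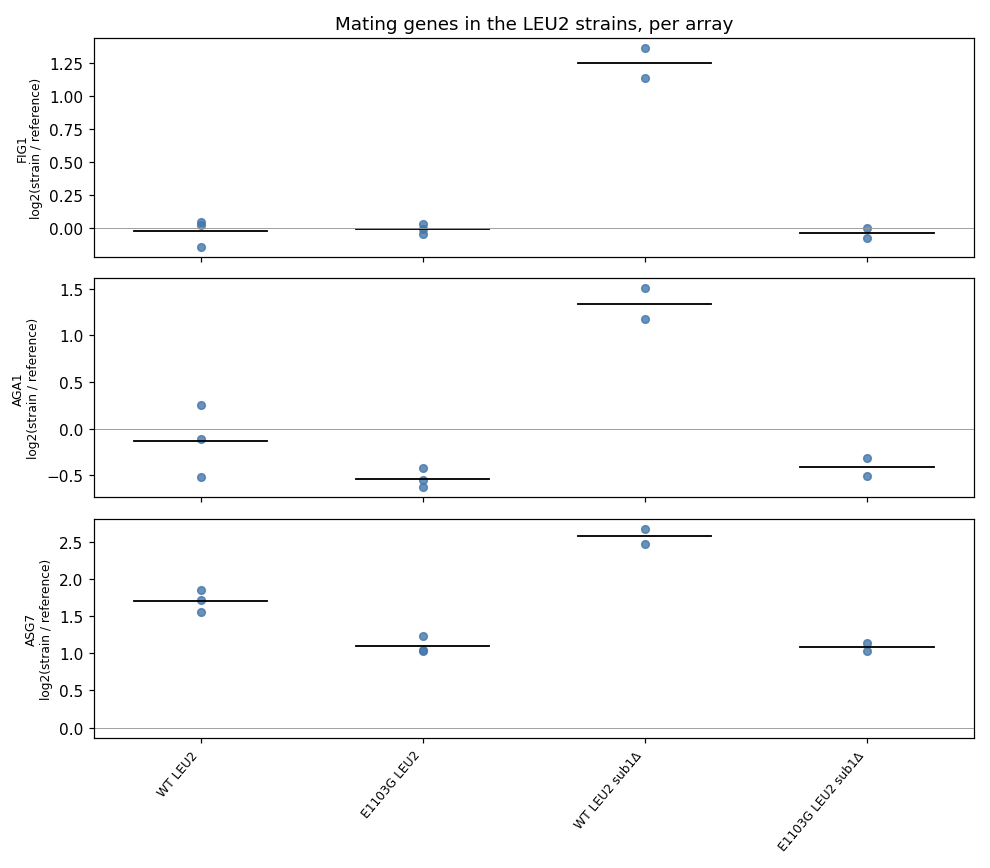
Log2 of strain over reference for the mating genes FIG1, AGA1 and ASG7 on each LEU2 array (points), adjusted for dye and reference pool, with group means (lines). The 2 arrays of the sub1-deleted wild type lie above every other array for all these genes, and FIG1 changed by 1.28 in that comparison.

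In the fit of all 57 arrays, the interaction of the SUB1 deletion with E1103G was tested as a contrast of the 10 LEU2 arrays. It was negative for AGA1 (-1.34 ± 0.19), FIG1 (-1.31 ± 0.09), IMD2 (-1.24 ± 0.23), ASG7 (-0.88 ± 0.10) and IMD3 (-0.83 ± 0.18), and positive for SIT1 (1.10 ± 0.21) and the glycine cleavage gene GCV1 (1.01 ± 0.21). The test called 21 genes, 5 positive and 16 negative. Without array 1 of the sub1-deleted wild type it called 7, all negative, with AGA1 at -1.17, FIG1 at -1.19 and ASG7 at -0.77 among them. Among pheromone response genes, 8 of 16 measured members fell and 8 did not pass the test (11 lower adjusted over the list alone), with a camera adjusted p = 7.67e-40 and adjusted p = 4.43e-08 with an estimated correlation, where fell means a negative interaction. Without array 1, which leaves 1 array of the sub1-deleted wild type, the median interaction of these 16 genes was -0.36. Among a-specific genes, 2 of 7 measured members fell and 5 did not pass the test (4 lower adjusted over the list alone), with a camera adjusted p = 1.15e-12 and adjusted p = 0.0137 with an estimated correlation, and without array 1, 1 was negative with adjusted p = 0.108 with an estimated correlation. The α-specific genes did not pass one by one: 0 of 4 measured members passed the test (0 adjusted over the list alone), with a camera adjusted p = 0.00231 and adjusted p = 0.151 with an estimated correlation. The count was 19 with median centring in place of loess (7 higher and 12 lower), 13 without the pool term, 5 from only the arrays of the same subunit and marker, 10 without the dimmest 25 percent of genes, 10 without sub1-deleted E1103G array 1, 7 without sub1-deleted wild-type array 1 and 10 without sub1-deleted E1103G array 2. IMD3 lost its call with median centring in place of loess (log2 change -0.54, adjusted p = 0.263), with only the pool 3 LEU2 arrays (0.0887) and on leaving out E1103G (LEU2) array 1 (0.107), E1103G (LEU2) array 2 (0.112), sub1-deleted E1103G array 1 (0.17), wild-type (LEU2) array 2 (0.0556), sub1-deleted wild-type array 1 (0.216), sub1-deleted E1103G array 2 (0.178), wild-type (LEU2) array 3 (0.117) or sub1-deleted wild-type array 2 (0.11). IMD2 lost its call with print-tip loess (log2 change -0.75, adjusted p = 0.448) and on leaving out sub1-deleted E1103G array 1 (0.0704), sub1-deleted wild-type array 1 (0.0949) or sub1-deleted E1103G array 2 (0.0738). GCV1 lost its call without the pool term (adjusted p = 0.251), from only the arrays of the same subunit and marker (0.32) and on leaving out E1103G (LEU2) array 2 (0.0669), sub1-deleted E1103G array 1 (0.168), sub1-deleted wild-type array 1 (0.0681), E1103G (LEU2) array 3 (0.0685), sub1-deleted E1103G array 2 (0.125), wild-type (LEU2) array 3 (0.0908) or sub1-deleted wild-type array 2 (0.168). SIT1 lost its call from only the arrays of the same subunit and marker (adjusted p = 0.0933) and on leaving out sub1-deleted E1103G array 1 (0.103), sub1-deleted wild-type array 1 (0.126), sub1-deleted E1103G array 2 (0.0738) or wild-type (LEU2) array 3 (0.0505). AGA1 lost its call from only the arrays of the same subunit and marker (adjusted p = 0.343). ASG7 lost its call from only the arrays of the same subunit and marker (adjusted p = 0.0848). The alpha specific list lost its call without sub1-deleted wild-type array 1 (adjusted p = 0.282).

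Of the strains with 1 array, 16 could be tested by taking the spread from the other groups, which assumes that the lone array varies like them. The arrays of N445Y, A349V, Y804C, D1502G and S713P have no rpb1 wild-type (URA3) array of the same dye and pool. N445Y gave the most calls, 2387, with MSC1 higher by 2.37 ± 0.35, SER3 by 2.14 ± 0.22 and the aldehyde dehydrogenase ALD3 by 2.06 ± 0.27, and MF(ALPHA)2 lower at -4.40 ± 0.32 and YHB1 at -2.12 ± 0.23. D526G called 1010, with MEP2 higher by 1.64 ± 0.26, HSP42 by 1.60 ± 0.41 and DBP2 lower at -1.46 ± 0.30. Y804C called 336, with MEP2 higher by 1.93 ± 0.26 and DUR3 by 1.57 ± 0.21. A349V called 333, with SER3 higher by 1.7 and the methionine synthase MET6 lower at -1.7. Without a wild-type (URA3) array, A349V called 208 (array 3) and Y804C 216 (array 1). HSP42 in D526G lost its call without the pool term (adjusted p = 0.0507).

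I1327V called 84 genes and S713P 66, and IMD2 was lower in both, at -1.05 ± 0.21 and -1.09 ± 0.21. TYE7 fell by 1.08 ± 0.18 in I1327V, by 1.15 ± 0.18 in S713P and by 1.11 ± 0.18 in A1076T. A1076T called 17, M1079V 9, and the combination of F1086S with E1103G 7. In that combination PRM7 was lower at -1.55 ± 0.24, and TRS31, a vesicle tethering gene, was higher by 0.51 ± 0.10. TRS31 was higher in A1076T by 0.65 ± 0.10 and in M1079V by 0.59 ± 0.10. D1502G called 0 genes by limma, with 169 at an unadjusted p below 0.05. Without a wild-type (URA3) array, S713P called 40 (array 1) and 27 (array 3), A1076T 8 (array 1) and 7 (array 2), M1079V 5 (array 3), and the combination 2 (array 1) and 2 (array 2). TRS31 in A1076T lost its call with median centring in place of loess (adjusted p = 0.149) and without the dye term (0.136). TRS31 in F1086S+E1103G lost its call with median centring in place of loess (adjusted p = 0.77), with print-tip loess (0.0553), without the dye term (0.721), without the pool term (0.28) and on leaving out wild-type (URA3) array 1 (0.117), wild-type (URA3) array 2 (0.0796) or wild-type (URA3) array 3 (0.0671). TRS31 in M1079V lost its call with median centring in place of loess (adjusted p = 0.151) and without the dye term (0.0573).

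Across genes, the changes of alleles left out of the classes were set against the fast minus slow difference, which shares no array with them. S713P (r = 0.513) and I1327V (r = 0.508) correlated positively, as did A1076T (r = 0.481) and M1079V (r = 0.432). E1103G in the LEU2 set, an allele of the fast class, gave r = 0.310, below each of these. Their Spearman rho was 0.42, 0.40, 0.34 and 0.30, against 0.18 for E1103G (LEU2). Set against that difference, the values thus do not show these alleles to be fast. N479A (r = -0.711), N479S (r = -0.649), D526G (r = -0.520) and N445Y (r = -0.503) correlated negatively, and the double mutant lay at -0.03. These are among 24 correlations across genes with the fast minus slow difference, with no test. Against the E1103G (LEU2) profile, also untested, M1079V gave r = 0.63, A1076T 0.60, S713P 0.54 and I1327V 0.49. The fast class gave 0.78 (E1103G) and 0.71 (L1101S), and the slow class 0.35 (H1085Q), 0.31 (F1086S) and 0.31 (N1082S). By that measure M1079V, A1076T, S713P and I1327V lay between both classes, as did F1086S+E1103G (0.57) and the double mutant (0.57).

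The rpb2 mutants (1 array each) were compared with 2 rpb2 wild-type arrays. In the second of these MET17, a sulfur amino acid enzyme, was at 30.9 times background in the strain channel against 2.46 in the first and 1.24 to 2.94 on the other 56 arrays of the series, so MET17 was not compared. Whether this array is of another strain is not known, and that would touch every rpb2 comparison, so counts without it are given. H1141R called 1429 genes, with the zinc transporter ZRT1 higher by 2.56 ± 0.20 and MF(ALPHA)2 lower at -2.70 ± 0.34. R120C called 790, with IMD2 lower at -1.89 ± 0.22 and IMD3 at -1.55 ± 0.17. G977S called 323 and D399H 256, and CHA1 was lower in both, at -1.76 ± 0.14 and -1.96 ± 0.14. E328K called 128, with IMD2 lower at -1.85 ± 0.22 and the phosphate transporter PHO84 higher by 0.90 ± 0.23. R595G called 31. Without rpb2 wild-type array 1 the calls were 112 in D399H, 60 in E328K and 190 in G977S. Without array 2 they were 992 in H1141R, 358 in R120C, 133 in G977S, 128 in D399H, 90 in E328K and 10 in R595G. PHO84 in E328K lost its call with median centring in place of loess (adjusted p = 0.162), without the pool term (0.82) and without rpb2 wild-type array 1 (0.235).

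The rpb7 mutant D166G and its wild type had 1 array each, so the difference has no replicate check and no test. The log2 difference of mutant minus wild type was -1.42 for IMD2, -1.15 for MF(ALPHA)2 and 0.67 for the a-pheromone gene MFA1.

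The mRNA of the mutated subunit moved in many strains. RPO21 rose in 10 of the 11 replicated rpb1 alleles on the URA3 plasmid, by up to 1.10 in H1085Q, and in R1399G it was at 0.15. Of the 10 rpb1 alleles with 1 array, RPO21 rose in 4 and did not pass in 6, with values from 0.19 to 1.04. The 11 alleles share 4 wild-type arrays, so these counts are not independent of each other. RPB2 rose in all 6 rpb2 alleles, by 0.78 to 1.87, while RPO21 passed in none of these 6. These 6 alleles share 2 rpb2 wild-type arrays, among them the array that carried MET17. The RPB2 values without that array are not given here. IMD2 rose in 7 of the 11 replicated rpb1 alleles and fell in 2. Of the α-specific genes MF(ALPHA)2 fell in 10 of the 11, SAG1 in 10 and STE3 in 8, and MF(ALPHA)1 passed in 0, with values from -0.33 to -0.08.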

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

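Both interaction tests and the search for an array apart were set before the data were examined, while the test of the E1103G effects of both strain sets, the external controls and every test of an explanation in this part were chosen only after the result was seen.

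The effect of the SUB1 deletion differed between the wild type and E1103G for 21 genes by limma's interaction test, 5 positive and 16 negative, with pheromone response genes foremost. Without array 1 of the sub1-deleted wild type, whose reference channel held URA3 signal, the interaction called 7 genes, 0 positive and 7 negative, while the median SUB1 change of the 16 pheromone response genes in the wild type was still 0.51, which argues against this array as the whole cause of the pheromone response. That median rests on the 1 sub1-deleted wild-type array left. Control arrays that read low would lift the E1103G effect in this set over that in the URA3 set, which has other controls. The median difference of these effects over the 16 genes was 0.012 ± 0.099 (SD over genes), against the SUB1 change of 0.55 to be explained, which argues against such controls if E1103G acts alike in both sets. Some α cells in the culture, whose pheromone could act on a cells, cannot be told apart from a response of the a cells themselves, since all 4 α-specific genes on array 1 (median shift 0.77), and 3 of 4 on array 2 (0.17), lay above every wild-type LEU2 array.

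The combination of H1085Q with E1103G departed from the sum of both single changes for 492 genes by limma's interaction test. MF(ALPHA)2 changed by -2.35 in H1085Q, -2.94 in E1103G and -2.25 in the double mutant, and SER3 by 1.91, 2.45 and 2.28. A change of like size in all these strains gives a departure of opposite sign by itself. For such genes the call does not show that the mutations act on each other. IMD2, which rose in H1085Q and fell in E1103G, is not of that kind.

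The E1103G effect differed between the LEU2 and the URA3 strain set for 13 genes by limma, and the α-specific genes among them fell in the URA3 set, whose cells carry α mRNAs. In the LEU2 set, whose cells carry a mRNAs, such genes have little room to fall. For them the mating types alone could give this difference. Over the 11 replicated rpb1 URA3 alleles the median change of the 4 α-specific genes ran from -1.35 to -0.20, against the same 4 wild-type arrays. In the 6 rpb2 alleles, which have their own controls, the middle value of that median was -0.89, and -0.70 without the rpb2 wild-type array that carried MET17, which argues against rpb1 wild-type arrays that read high. The highest median of the a-specific genes over the 11 alleles was 0.083, which argues against a cells in the mutant cultures. Growth state of the cultures stays open beside an effect of the mutations themselves, and neither was tested.

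External control RNAs, of which 4 of 14 were bright, were set in rpb1 URA3 mutants against their wild type after each array was centred on yeast genes. The log2 ratio of strain over reference was 0.71 ± 0.28 (SD, n = 33 arrays) against 0.42 ± 0.08 (SD, n = 4), a difference of 0.29 (two-sided exact permutation p = 0.0425 over single arrays). With 1 value per allele, since many alleles have 2 or 3 arrays, the difference was 0.27 (two-sided exact permutation p = 0.0771), which does not pass, and 17 of 21 alleles lay above the wild-type mean and 4 below. The other wild types varied: the LEU2 one lay at 0.58 (n = 3), and those of rpb2 at 0.90 (n = 2) and rpb7 at 1.05 (n = 1) lay above the mean of the rpb1 mutants, while the rpb7 mutant at 0.51 lay below its wild type. Within arrays of 1 dye orientation and reference pool the differences were 0.28 and 0.30, which argues against dye or pool as the cause. Uneven pipetting of the control RNA cannot be told apart, since the ratios of replicate arrays over 13 groups of 2 had a Spearman rho of 0.374 (permutation p = 0.208) and a Pearson r of 0.165 (permutation p = 0.587), or 0.334 without the 2 farthest groups. Less mRNA per total RNA in the mutants could also raise the ratio, which was not tested. The difference was 0.29 without background correction, 0.24 with median centring and 0.30 in the authors' values.

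YRO2 was at -0.37 on 1 of the 4 wild-type (URA3) arrays, far from the other values, which was the 1 case among 49 genes looked at, where chance gives about 1 in 20.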

How the results depend on the processing

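Testing all yeast probes, those without a gene name included, was chosen only after the data were seen, as were the fits without array 1 of the sub1-deleted wild type, those of strains with 1 array without a wild-type array, the splits of whole alleles and the external controls by allele, and the other alternatives were fixed in advance.

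Of 346 gene calls that the naming rule gave, 259 kept their direction and their side of the threshold under every alternative run on single genes, which leaves out the 1.7-fold threshold and all yeast probes, and 87 did not under at least 1, among them 71 under one other than leaving out 1 array. Calls lost were 41 with median centring, 37 without the pool term, 25 without the dye term, 28 of 310 from only arrays of the same subunit and marker, 9 of 82 with only pool 3 arrays, 13 with print-tip loess and 1 more that also changed sign (GPM1), 12 in the authors' values, 2 without background correction and 2 of 285 without the dimmest 25 percent of genes. With 1 array left out, 162 of 2082 were lost. Of 153 list calls at the preset correlation, 15 held with an estimated one. Print-tip loess and no background correction left all 20 main values within 1.5 times or their spread. No scaling moved the median over all genes by more than 0.1. Signal over background limits the dim genes, which were tested with the others. Except for fewer arrays or genes in a fit, the cause of a change was not tested.

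With median centring the count of called genes was 776 in E1103G (URA3), 870 in L1101S, 413 in N479A, 697 in D668G, 909 in E822K, 354 in R1399G, 1120 in the double mutant, 661 in E1103G (LEU2), 270 for the H1085Q by E1103G interaction and 4548 over the strains with 1 array. Without the pool term it was 7.7e2 in E1103G (URA3; 345 higher and 426 lower), 828 in L1101S, 1201 in N1082S, 313 in N479A, 569 in D668G, 8.0e2 in E822K, 345 in R1399G, 1040 in the double mutant, 767 in E1103G (LEU2), 72 for SUB1 in the wild type, 13 for its interaction, 241 for the H1085Q interaction and 3919 over the strains with 1 array.

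The replicate letter in the labels goes with the dye orientation, so the fit without the dye term is the one with no replicate block. It called 869 genes in E1103G (URA3), 421 in N479A, 686 in D668G, 293 in R1399G, 109 for SUB1 in the wild type, 1 for SUB1 in E1103G and 253 for the H1085Q interaction. Replicate numbers do not pair the arrays: over 13 groups of 2, the differences between both arrays correlated between groups at -0.684 to 0.615 (median 0.194), and in 1 group replicate 1 was in Cy5.

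From only arrays of the same subunit and marker the count was 784 in E1103G (LEU2), 56 for SUB1 in the wild type and 5 for its interaction. It was 135 for SUB1 in the wild type with only pool 3 arrays, and 10 for its interaction without the dimmest 25 percent of genes. The correlation of both E1103G profiles was 0.815 in the authors' values and 0.824 over all yeast probes.

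A threshold that also asks for a change over 1.7-fold left 73 genes in E1103G (URA3; 15 higher and 58 lower), 65 in L1101S (16 and 49), 116 in H1085Q (68 and 48), 82 in N1082S (48 and 34), 91 in F1086S (57 and 34), 129 in N479S (81 and 48), 19 in N479A (12 and 7), 43 in D668G (30 and 13), 49 in E822K (26 and 23), 22 in R1399G (7 and 15), 67 in the double mutant (29 and 38), 48 in E1103G (LEU2; 10 and 38), 22 for SUB1 in the wild type (12 and 10), 11 for its interaction (2 and 9), 59 for the H1085Q interaction (37 and 22), 123 for fast against slow (23 and 100) and 794 over the strains with 1 array.

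Leaving out 1 array gave 512 to 1161 genes in E1103G (URA3), 386 to 1388 in L1101S, 1275 to 2076 in H1085Q, 493 to 1880 in N1082S, 844 to 1792 in F1086S, 2277 to 2568 in N479S, 90 to 881 in N479A, 320 to 9.8e2 in D668G, 544 to 1310 in E822K, 121 to 4.5e2 in R1399G, 784 to 1596 in the double mutant, 889 to 1349 in E1103G (LEU2), 35 to 556 for SUB1 in the wild type, 1 to 3 for SUB1 in E1103G, 7 to 26 for its interaction, 192 to 447 for the H1085Q interaction, 2209 to 2794 for fast against slow and 5960 to 6909 over the strains with 1 array. The lone array left in a group is then assumed to vary like the others. The correlation was 0.655 to 0.815 for both E1103G profiles and 0.238 to 0.392 for H1085Q.

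Of values named in the text, GPM1 in E1103G (URA3) turned to 0.47 with print-tip loess. Others kept their calls but moved by more than 1.5 times. With print-tip loess URA2 was at 0.51 in H1085Q, 0.65 in N479A, -0.76 for the H1085Q interaction and -0.51 for fast against slow, IMD4 at 0.73 in H1085Q and PGI1 at -0.41 in E1103G (URA3). In the authors' values URA2 was at 0.66 in N479A and -0.81 for fast against slow, and PGI1 at -0.31 in E1103G (URA3). With median centring HSC82 was at 0.54 in H1085Q. In E822K the medians of lists with no call changed sign, to 0.12 for sulfur genes without the dimmest 25 percent of genes, and with 1 array left out for galactose genes (-0.012 to 0.032) and Gcn4 genes (-0.38 to 0.28), where E822K array 1 or 2 was the one left out.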

Other observations

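The comparisons with other splits of the arrays in this part were set before the data were examined, and the marker channels were looked at only after the result was seen.

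Genes of GTP and pyrimidine synthesis moved in further comparisons. In N1082S, 5 of 6 measured members rose and 1 did not pass the test (5 higher adjusted over the list alone), with a camera adjusted p = 3.42e-06 and adjusted p = 0.101 with an estimated correlation. In F1086S, 5 of 6 measured members rose and 1 did not pass the test (5 higher adjusted over the list alone), with a camera adjusted p = 2.37e-05 and adjusted p = 0.124 with an estimated correlation. In N479S, 5 of 6 measured members rose and 1 did not pass the test (5 higher adjusted over the list alone), with a camera adjusted p = 2.95e-05 and adjusted p = 0.122 with an estimated correlation. For the interaction of the SUB1 deletion with E1103G, 2 of 6 measured members fell and 4 did not pass the test (4 lower adjusted over the list alone), with a camera adjusted p = 1.13e-08 and adjusted p = 0.0112 with an estimated correlation, where fell means a negative interaction. Without array 1 of the sub1-deleted wild type, 0 of the 6 passed, with adjusted p = 0.0394 with an estimated correlation.

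Pheromone response genes fell in α cells of other alleles as well. In H1085Q, 1 of 16 measured members rose, 12 fell and 3 did not pass the test (2 higher and 12 lower adjusted over the list alone), with a camera adjusted p = 0.000572 and adjusted p = 0.106 with an estimated correlation. In N479S, 1 of 16 measured members rose, 13 fell and 2 did not pass the test (1 higher and 13 lower adjusted over the list alone), with a camera adjusted p = 0.000792 and adjusted p = 0.122 with an estimated correlation. For the interaction of the SUB1 deletion with E1103G, among iron regulon genes, 1 of 16 measured members rose and 15 did not pass the test (7 higher adjusted over the list alone), with a camera adjusted p = 1.96e-09 and adjusted p = 0.047 with an estimated correlation, where rose means a positive interaction. Without array 1 of the sub1-deleted wild type, 0 of the 16 iron genes passed, with adjusted p = 0.0394 with an estimated correlation. For N479S: The pheromone response list lost its call with median centring in place of loess (adjusted p = 0.0594).

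Other splits of the same arrays were run for the comparisons with 3 or more arrays a side. N479S against wild type called 2748 genes, and among 35 splits 1 gave as many, the real one, with 1762 the highest of the others. That is the smallest share that 35 splits can reach. Of the 3 N479S arrays 2 are of 1 isolate, and splits of isolates would be too few for a share under 0.05, so chance is not excluded. Fast against slow as 2 pooled classes called 2754, and among 100 splits 1 gave as many, the real one, with 1806 the highest of the others. These splits part the 2 arrays of an allele, and the 10 splits of whole alleles, run after the result was seen, are too few for a share under 0.05, with 1503 genes in the highest other. For E1103G (LEU2) the 10 splits of 6 arrays are too few for a share under 0.05, with 1296 genes in the real split and 512 in the highest other.

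In the reference channel, URA3 signal lay between 1.99 and 13.9 times background on the 47 arrays of the URA3 strain set. On array 2 of the rpb2 wild type the log2 ratio of MET17 was 0.29, against -4.45 on array 1.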
